A study of Homo sapiens with 18 samples.

How the data were processed

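RNA was measured in 18 libraries from the B cell lymphoma lines Ramos and LY1, with 3 libraries each of untreated control cells, cells given N-acetylcysteine (NAC) and cells given vitamin C (VitC), all at 24 h. Per the labels, total RNA was taken with the RNeasy Plus Mini kit and sequenced on a HiSeq 2000. The doses, the library kit and its strandedness are not given in the sources used here, nor is how the 3 libraries of a group were cultured.

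Per the labels, the authors aligned reads to GRCh38 with STAR, counted them with featureCounts and used DESeq2, with no versions given. Each line has its own table of 60666 genes. The signal in the deposited tables is reads per gene divided by 1 size factor per library, made by the authors within the 9 libraries of a line, so the 2 tables are on separate scales. The log2 fold changes of NAC and VitC against control in the same tables were computed by the authors. The p-values and adjusted p-values of those comparisons were also computed by the authors, as deposited. The authors' values were used here only for comparison. In every library 100% of the values were whole multiples of a single step within 0.001 read, so the whole reads per gene were recovered by division. In LY1 NAC replicate 1 and Ramos control replicate 3 the step lay close to 1, and their reads were recovered in the same way. Recovered reads summed to between 20188487 and 25387312 per library. Between replicates the variance per gene, as a mean over genes, was 1.28 to 9.46 times that of counting noise. The highest values belonged to pairs with Ramos NAC replicate 2.

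The comparisons, tests, lists, rule for named genes and most alternatives were chosen before the data were examined. The plan named edgeR for raw counts and, for normalized values, limma-trend, which was therefore the main test. Within each line log2(deposited value + 1) was fitted with group means over 9 libraries in R 4.3.3 with limma 3.58.1 (eBayes with trend and robust). Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), p was adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. The difference of the NAC effects, the difference of the VitC effects and the comparison of the controls used all 18 libraries, with recovered reads divided by joint median-of-ratios size factors. The plan had reserved these 3 comparisons for tables of raw counts, and they were run on the recovered reads. The lines were processed in separate tables, so line cannot be told apart from batch.

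Genes were named by a fixed rule. MYC and EGR1 were given in every comparison. In each comparison with control the 8 largest rises and 8 largest falls were named among called genes with a symbol, a mean CPM (counts scaled to library size) of at least 5 over the 6 libraries and every treated library beyond every control library, in 3 of 3 libraries. In the other comparisons 5 and 5 were named. Up to 4 members of each list with the smallest adjusted p could be named. Y-linked genes, XIST and immunoglobulin and T cell receptor segments were left out. A name derived from a sequenced clone was not taken as a symbol, a reading of the rule made after the data were seen. A gene not past the threshold was named only where a gene called in 1 comparison was followed in another. Where a group summed to 30 reads or fewer, the ratio of summed reads is given with its exact 95% counting interval, and against a group without reads a bound from 3 reads over the group.

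The 34 gene lists, with 1196 entries in all, were written by hand. They covered MYC targets, immediate early genes, p53 targets, the BCL2 family, caspases and death receptors, NRF2 targets, glutathione and thioredoxin enzymes, ATF4 targets, the unfolded protein response, hypoxia targets, glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded messenger RNAs, sterol synthesis, iron genes, metallothioneins and heat shock genes. They also covered G1/S and replication genes, G2/M and mitosis genes, ribosomal proteins, replication-dependent histones, NF-kappaB targets, interferon response genes, B cell receptor and identity genes, germinal centre genes, plasma cell genes, MHC class II genes, ascorbate transport, dioxygenase and DNA methylation genes, germline genes silenced by methylation, lysosome and autophagy genes, collagen and prolyl hydroxylation genes, and markers of T and NK cells, myeloid cells and stromal or epithelial cells. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, and an estimated correlation beside it) on the same log2 values, adjusted over the lists of a comparison. A list call was taken as firm only where it also passed with the estimated correlation. Member counts are over all genes tested, and adjusted over the list alone where stated. In the 3 comparisons across lines members were counted and no list test was run. Some single genes are not reported here.

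The alternatives were TMM scaling, scaling to total reads, no filter, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, replicate number as a block, only the compared groups in the fit, all 18 libraries in 1 fit, a minimum fold of 1.5, a pseudocount of 0.1 without a filter, each library left out in turn, and for lists the estimated correlation and fry. Where a library was left out of a group, the remaining 2 were fitted with the spread pooled over the groups. Added after the data were seen were edgeR quasi-likelihood on the recovered reads and a correction for transcript length and GC share. For the correction each library's lowess trend (span 0.3, 3 rounds) along log2 length and GC share of the longest GENCODE 29 transcript, among genes with a mean log2 value of at least 5, was taken out within its line. It was not applied to the comparison of the controls. Replicate numbers did not pair across groups (correlations of -0.0434 to 0.0312 between libraries with equal numbers and -0.0526 to 0.0557 between others, against a minimum of 0.1), so no block was used in the main test.

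The main test was run on simulated reads with the depth and spread of these libraries, for the 4 comparisons with control. It recovered 51 to 68.1% of genes changed by 1.25-fold, 77.1 to 84% at 1.5-fold, 90 to 96% at 2-fold and 98 to 100% at 4-fold. Of its calls 2.44 to 8.24% were of unchanged genes. Few genes were changed in the simulation, and its noise was independent between genes. The real comparisons called 15.8 to 55.9% of genes and carried length and GC trends, so these shares need not hold for them. The authors called 1873 genes with NAC and 2018 with VitC in Ramos and 7018 and 7261 in LY1 at an adjusted p under 0.05. Of these 1839, 1977, 6845 and 7204 were also called here, all in the same direction. For MYC the authors' log2 changes were 0.02 (adjusted p = 0.804) and 0.31 (1.16e-14) in Ramos and -0.24 (3.31e-28) and -0.28 (7.26e-37) in LY1. For EGR1 they were -0.51 (0.266), -0.57 (0.198), 1.21 (4.41e-08) and -0.22 (0.525).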

Results

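The series measured transcripts in 2 human B cell lymphoma lines, Ramos (Burkitt lymphoma) and LY1 (diffuse large B-cell lymphoma), both labelled as high in CMYC expression. Cells were left untreated or were given N-acetylcysteine (NAC) or vitamin C (VitC) for 24 h, and total RNA of 3 libraries per group, 18 in all, was sequenced on a HiSeq 2000. Depth ran from 20188487 reads assigned to genes in the smallest library to 25387312 in the largest. Each line was fitted by itself in its 9 libraries, and all changes below are log2 changes over that line's control unless stated. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p-value measures the spread between these libraries, which may be technical.

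Reads from the mitochondrial chromosome took a larger share of the library after treatment, most in LY1: 5.89 ± 0.0399% in its controls, 9.41 ± 0.149% with NAC and 11.2 ± 0.226% with VitC, against 4.64 ± 0.0728%, 4.91 ± 0.109% and 6.25 ± 0.065% in Ramos (mean ± SD, 3 libraries each). Changes also ran with transcript length and GC share across genes. The rank correlation of the log2 change with length was -0.154 for NAC and -0.274 for VitC in Ramos, and -0.319 and -0.428 in LY1. With GC share it was -0.362 and 0.063 in Ramos, and 0.443 and 0.482 in LY1. In LY1 the fifth of genes with the shortest transcripts had a median change of 0.10 with NAC and 0.15 with VitC, and the fifth with the longest had -0.16 and -0.23.

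MYC moved in opposite directions with VitC in the 2 lines. In Ramos, VitC raised MYC from 13640 ± 167 to 16970 ± 513 normalized reads (log2 change 0.31, standard error 0.0339, adjusted p = 2.84e-06), higher in 3 of 3 libraries. With NAC it stood at 13830 ± 330 and was not called in Ramos (log2 change 0.02, standard error 0.0339, adjusted p = 0.755). In LY1, MYC fell from 11570 ± 150 to 9817 ± 161 with NAC (log2 change -0.24, standard error 0.02, adjusted p = 4.81e-14). It fell to 9564 ± 19.1 with VitC (log2 change -0.28, standard error 0.02, adjusted p = 3.62e-16), lower in 3 of 3 libraries each time. EGR1, an immediate early transcription factor, rose 2.29-fold with NAC in LY1, from 50.2 ± 7.13 to 116 ± 12 (log2 change 1.2, standard error 0.159, adjusted p = 1.33e-08), higher in 3 of 3 libraries. It was not called with VitC in LY1, at 43.2 ± 3.16 (log2 change -0.20, adjusted p = 0.286). In Ramos, EGR1 stood at 41.4 ± 6.06 in controls, 29 ± 0.783 with NAC and 27.8 ± 1.46 with VitC. It was called in neither (log2 change -0.49, adjusted p = 0.0898, and log2 change -0.55, adjusted p = 0.0569). EGR1 passed the threshold in Ramos when all 18 libraries were fitted together (adjusted p = 0.0387 with NAC and 0.0164 with VitC). With VitC it also passed with libraries scaled to total reads (0.0423), with only the compared groups fitted (0.046) and with the length and GC trends removed (0.0419). Over all its alternatives the adjusted p ran from 0.0387 to 0.297 with NAC and from 0.0164 to 0.215 with VitC.

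**Figure D1:**
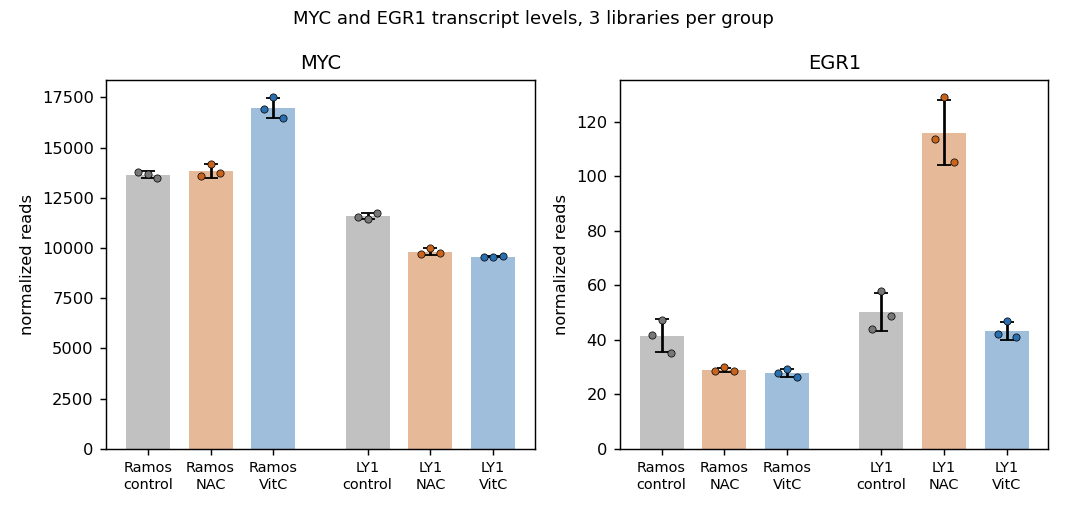
MYC and EGR1 in each library (dots) as normalized reads, with bars for the mean and whiskers for the SD of 3 libraries in Ramos and LY1 under control, NAC and VitC. The 2 lines were scaled separately, so heights compare within a line.

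In Ramos, NAC raised genes of the amino acid and endoplasmic reticulum stress responses and of antigen presentation, and lowered genes of sterol and fatty acid synthesis. DDIT4, an mTORC1 inhibitor, rose 2.99-fold, from 190 ± 26.6 to 567 ± 22.8 normalized reads (log2 change 1.58, standard error 0.081, adjusted p = 2.54e-10). The stress transcription factor ATF3 rose 2.14-fold (from 81.6 ± 6.50 to 176 ± 11, adjusted p = 1.09e-06) and the activin subunit gene INHBE rose 1.85-fold (adjusted p = 1.98e-08). CCPG1, a receptor for autophagy of the endoplasmic reticulum, rose 2.02-fold, and its readthrough transcript DNAAF4-CCPG1, which overlaps it, rose 1.99-fold. The septin SEPTIN11 rose 2.15-fold, the adhesion receptor ADGRL2 2.12-fold and the chemokine receptor CCR7 1.88-fold (adjusted p = 0.000266). The largest falls were in MYH7B, a myosin heavy chain (to 0.419 times control, from 616 ± 26.4 to 257 ± 13.2, adjusted p = 4.66e-10) and the Notch coactivator MAML3 (0.633). The teneurin TENM1 (0.636), the ubiquitin ligase gene PDZRN4 (0.649) and the transcription factor ZFHX4 (0.654) also fell. The lipogenic regulator THRSP fell to 0.667 times control and the lincRNA OLMALINC, which lies beside SCD, to 0.683. In a fit of all 18 libraries together TENM1 (adjusted p = 0.185, the highest of its alternatives) and ZFHX4 (0.338, likewise) were no longer called.

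Among gene lists in Ramos with NAC, 4 were called with a preset and with an estimated correlation between genes. Of 41 ATF4 targets tested, which serve amino acid supply and stress, 22 rose and 2 fell (28 and 3 adjusted over the list alone, list adjusted p = 1.48e-14). WARS1 (log2 change 0.45) and PSAT1 (0.43), of amino acid charging and serine synthesis, were among them. Of 31 sterol synthesis genes 20 fell and 11 did not pass (22 fell and 1 rose adjusted over the list alone, list adjusted p = 9.57e-16). Among them were fatty acid synthase FASN (-0.51), LSS (-0.51) and HMGCS1 (-0.45). Of 13 MHC class II genes 11 rose, 11 also adjusted over the list alone (list adjusted p = 7.01e-15). They included HLA-DRA (log2 change 0.63, standard error 0.0368, adjusted p = 1.21e-09), HLA-DQA1 (0.55) and HLA-DMA (0.45). Reads can be shared between HLA paralogs, and HLA-DRA was no longer called when all 18 libraries were fitted together (adjusted p = 0.0795, the highest of its alternatives). Of 32 genes of the unfolded protein response 11 rose and 1 fell (13 and 1 adjusted over the list alone, list adjusted p = 2.6e-05). They included the chaperones DNAJB9 (0.66) and HSP90B1 (0.29) and the translocon gene SEC61B (0.40).

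The other called lists in Ramos with NAC passed with the preset correlation only. Higher were glutathione and thioredoxin genes (8 of 33 rose, 10 rose and 1 fell adjusted over the list alone, adjusted p = 0.000223, and 0.283 with an estimated correlation), among them CTH (0.62) and TXNIP (0.64). So were plasma cell and secretory genes (7 rose and 1 fell of 19, 8 and 1 adjusted over the list alone, adjusted p = 0.000223, and 0.0623 with an estimated correlation), among them BHLHA15 (1.21) and SEC11C (0.42). NF-kappaB targets were higher (10 rose and 1 fell of 31, 12 and 3 adjusted over the list alone, adjusted p = 0.00394, and 0.0524 with an estimated correlation), with PLEK at 0.71. Caspase and death receptor genes were higher (8 rose and 1 fell of 31, the same counts adjusted over the list alone, adjusted p = 0.00431, and 0.0524 with an estimated correlation), with FAS at 0.47 and CASP2 at -0.20. Hypoxia targets were higher (5 rose and 2 fell of 28, 8 and 2 adjusted over the list alone, adjusted p = 0.00746, and 0.0615 with an estimated correlation). So were lysosome and autophagy genes (5 rose and 1 fell of 32, 6 and 1 adjusted over the list alone, adjusted p = 0.0151, and 0.064 with an estimated correlation), with MAP1LC3B at 0.41. Lower were ascorbate transport, dioxygenase and DNA methylation genes (1 rose and 7 fell of 27, 2 and 12 adjusted over the list alone, adjusted p = 0.000643, and 0.283 with an estimated correlation), with DNMT1 at -0.18 and UHRF1 at -0.20. B cell receptor and identity genes were lower (2 rose and 10 fell of 35, 4 and 11 adjusted over the list alone, adjusted p = 0.0407, and 0.0959 with an estimated correlation), with SYK at -0.30 and CD38 at -0.28. The BCL2 family was not called (4 rose and 2 fell of 19, 5 and 2 adjusted over the list alone, adjusted p = 0.149), though BNIP3L (0.50) rose and BCL2L1 (-0.17) fell. MYC targets were not called (4 rose and 10 fell of 72, 6 and 11 adjusted over the list alone, adjusted p = 0.347). Nor were p53 targets (6 rose and 2 fell of 29, adjusted p = 0.0681) or NRF2 targets (5 rose and 3 fell of 29, 7 and 3 adjusted over the list alone, adjusted p = 0.148). Of the NRF2 list NQO1 (0.76), HMOX1 (0.67) and FTH1 (0.43) rose.

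Of 15075 genes tested in Ramos with NAC, 2380 were called, 1187 higher and 1193 lower, 36 and 25 of them by at least 2-fold, and 7 against a minimum fold of 1.5. NAC replicate 2 stood apart from the other NAC libraries. The variance per gene, as a mean over genes, was 8.92 and 9.46 times that of counting noise in its pairs. In the remaining pair it was 1.38 times. The medians over genes were 1.7 and 1.77 in its pairs, against 0.592. Relative to the mean of the other NAC libraries, levels in NAC replicate 2 fell with transcript length (rank correlation -0.511). The values of 0.367 and 0.390 for replicates 1 and 3 were each taken against a mean that includes replicate 2. Without this library 3309 genes were called. The count was 1123 without control replicate 1 and 1296 without control replicate 2. With the length and GC trends removed, 2299 were called, of which 1475 were called in the same direction by the main test. The ascorbate and dioxygenase list (adjusted p = 0.067) and the B cell receptor list (0.0996) were then no longer called, and ribosomal protein genes were called lower (12 of 78 fell, adjusted p = 0.00356, against 0.922 in the main test).

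In Ramos, VitC raised antioxidant and ferritin transcripts and lowered the transferrin receptor transcript. Heme oxygenase HMOX1 rose 7.65-fold, from 54.9 ± 1.69 to 426 ± 13.9 normalized reads (log2 change 2.94, standard error 0.104, adjusted p = 1.71e-13). The quinone reductase NQO1 rose 6.01-fold, from 89.1 ± 4.18 to 541 ± 45.1 (adjusted p = 2.17e-13). Ferritin heavy chain FTH1, whose reads can be shared with pseudogenes, rose 3.04-fold, from 5211 ± 145 to 15820 ± 469 (adjusted p = 2.44e-15). The transferrin receptor TFRC fell to 0.422 times control, from 17310 ± 522 to 7305 ± 271 (log2 change -1.25, standard error 0.0452, adjusted p = 2.17e-13). DDIT4 rose 4.19-fold, ATF3 2.89-fold, the cation-chloride cotransporter family gene SLC12A8 3.37-fold and the collagen gene COL24A1 4-fold. The mitochondrial ribosomal RNA MT-RNR1 rose 3.46-fold (adjusted p = 1.22e-16), more than the messenger RNAs of its chromosome, and nuclear copies can share its reads. Lower were the perforin-like gene MPEG1 (0.451 times control), the synaptic adhesion gene NLGN2 (0.558), SERINC2, a serine incorporator (0.570), and the PNMA family gene PNMA8C (0.585). The follicle homing receptor CXCR5 (0.590, from 378 ± 25.4 to 223 ± 28.7) and SLC9A3-AS1 (0.596), an antisense gene for which strand matters, also fell. The mitochondrial transfer RNA MT-TT fell to 0.504 times control (adjusted p = 0.0414). It was not called without control replicate 2 (0.127), control replicate 3 (0.119) or VitC replicate 3 (0.0737). Nor was it called with a pseudocount of 0.1 (0.0547), with only the compared groups fitted (0.0975) or with replicate number as a block (0.0938).

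Called with the preset and the estimated correlation in Ramos with VitC were 6 lists. Of 41 ATF4 targets 38 rose (39 adjusted over the list alone, adjusted p = 8.63e-46), with CHAC1, a glutathione-degrading enzyme, at 1.09, TRIB3 at 0.79 and PSAT1 at 0.59. Of 29 NRF2 targets 21 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 1.5e-22), with thioredoxin reductase TXNRD1 at 0.85 and ferritin light chain FTL at 0.77. Of 13 mitochondrially encoded messenger RNAs 11 rose (12 adjusted over the list alone, adjusted p = 2e-19), including MT-CO2 (0.49) and MT-ND1 (0.52). Of 31 sterol synthesis genes 21 fell (23 adjusted over the list alone, adjusted p = 1.34e-16), with HMGCS1 at -0.52 and LSS at -0.45. Of 35 B cell receptor and identity genes 22 fell and 1 rose (24 and 2 adjusted over the list alone, adjusted p = 3.11e-13). They included the B lineage transcription factors SPIB (-0.52) and PAX5 (-0.49) and the CD20 gene MS4A1 (-0.47). Of 32 interferon response genes 11 fell (14 adjusted over the list alone, adjusted p = 9.39e-06), including MX2 (-0.51), MX1 (-0.31) and OAS2 (-0.27).

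Another 10 lists passed in Ramos with VitC with the preset correlation only. MYC targets were higher, as MYC was (25 rose and 3 fell of 72, 33 and 3 adjusted over the list alone, adjusted p = 1.27e-08, and 0.0644 with an estimated correlation), among them SHMT2 (0.29) and EIF4A1 (0.23). So were ribosomal protein genes (42 of 78 rose, 58 adjusted over the list alone, adjusted p = 8.58e-20, and 0.331 with an estimated correlation), with RPL12 at 0.27. Also higher were glutathione and thioredoxin genes (10 of 33 rose, the same counts adjusted over the list alone, adjusted p = 0.000175, and 0.289 with an estimated correlation), with CTH at 0.89. Iron genes were higher (7 rose and 2 fell of 17, 8 and 4 adjusted over the list alone, adjusted p = 0.00917, and 0.0644 with an estimated correlation). Caspase and death receptor genes were higher (7 rose and 2 fell of 31, 9 and 2 adjusted over the list alone, adjusted p = 0.0176, and 0.0644 with an estimated correlation). They included CASP4 at 0.43 and the apoptosome gene APAF1 at -0.31. Hypoxia targets were higher (7 rose and 3 fell of 28, 9 and 3 adjusted over the list alone, adjusted p = 0.0155, and 0.0644 with an estimated correlation), with VEGFA at 0.51. Heat shock genes were higher (4 of 22 rose, 5 adjusted over the list alone, adjusted p = 0.0151, and 0.192 with an estimated correlation). So were nuclear-encoded respiratory chain genes (2 rose and 1 fell of 76, the same counts adjusted over the list alone, adjusted p = 0.0484, and 0.861 with an estimated correlation). Germinal centre genes were lower (2 rose and 10 fell of 24, 3 and 11 adjusted over the list alone, adjusted p = 0.00449, and 0.0536 with an estimated correlation), with GNA13 at -0.28. So were the 5 tested T and NK cell genes (2 fell, 2 also adjusted over the list alone, adjusted p = 0.0474, and 0.14 with an estimated correlation). The BCL2 family was not called (3 rose and 2 fell of 19, adjusted p = 0.571): PMAIP1 rose (0.29), and BMF (-0.40) and BCL2A1 (-0.66) fell.

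In Ramos with VitC 2507 of 15075 genes were called, 1201 higher and 1306 lower, 55 and 42 of them by at least 2-fold, and 33 against a minimum fold of 1.5. The count was 1488 without control replicate 2, 1561 without control replicate 3, 1615 without VitC replicate 2, 1641 without VitC replicate 3 and 1783 without control replicate 1. With only the compared groups fitted it was 4056. The main fit also pools the spread of the NAC libraries, which varied more (median SD of log2 values 0.101, against 0.0702 in controls and 0.0704 with VitC). With libraries scaled to total reads 821 genes were higher and 1830 lower. With the length and GC trends removed 3256 were called, 2222 of them in the same direction by the main test. The respiratory chain (adjusted p = 0.905) and heat shock (0.0672) lists were then no longer called, while G1/S genes (0.044) and MHC class II genes (7 of 13 fell, 0.0109) were called lower.

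Compared directly in Ramos, NAC left the antioxidant genes lower and the B cell genes higher than VitC did. HMOX1 was at 0.207 times its VitC level (log2 change -2.27, standard error 0.104, adjusted p = 1.43e-11), COL24A1 at 0.216, NQO1 at 0.281, SLC12A8 at 0.428 and FTH1 at 0.443. TFRC was 2.47-fold higher (log2 change 1.3, standard error 0.0452, adjusted p = 5.86e-13). MT-TT (2.97-fold, adjusted p = 0.00392), PDZRN3, a ubiquitin ligase (1.91-fold), the ciliary gene TCTN1 (1.85-fold) and the prenylcysteine oxidase PCYOX1 (1.83-fold) were also higher with NAC. MYC was lower with NAC (log2 change -0.29, standard error 0.0339), and EGR1 was not called (log2 change 0.06, adjusted p = 0.86). Lower with NAC were NRF2 targets (21 of 29 fell, 22 fell and 1 rose adjusted over the list alone, adjusted p = 1.12e-18). So were ATF4 targets (33 of 41 fell, 35 fell and 1 rose adjusted over the list alone, adjusted p = 8.43e-19) and mitochondrially encoded messenger RNAs (11 of 13, the same counts adjusted over the list alone, adjusted p = 1.21e-14). Higher with NAC were MHC class II genes (12 of 13, the same counts adjusted over the list alone, adjusted p = 1.38e-14) and the unfolded protein response (15 rose and 1 fell of 32, 17 and 1 adjusted over the list alone, adjusted p = 1.47e-05). So were B cell receptor and identity genes (17 rose and 2 fell of 35, 18 and 2 adjusted over the list alone, adjusted p = 3.79e-06) and interferon response genes (10 of 32 rose, 15 rose and 1 fell adjusted over the list alone, adjusted p = 0.000249). These 7 lists were called with the preset and the estimated correlation.

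With the preset correlation only, MYC targets (3 rose and 38 fell of 72, 4 and 40 adjusted over the list alone, adjusted p = 5.97e-09, and 0.0582 with an estimated correlation) and ribosomal proteins (50 of 78 fell, 64 adjusted over the list alone, adjusted p = 1.2e-16, and 0.4 with an estimated correlation) were lower with NAC than with VitC in Ramos. So were heat shock genes (1 rose and 10 fell of 22, 1 and 11 adjusted over the list alone, adjusted p = 0.00664, and 0.177 with an estimated correlation). Glycolysis (1 rose and 8 fell of 20, adjusted p = 0.012, and 0.31 with an estimated correlation) and iron genes (2 rose and 8 fell of 17, 3 and 9 adjusted over the list alone, adjusted p = 0.0271, and 0.109 with an estimated correlation) were lower too. NF-kappaB targets (12 rose and 5 fell of 31, 13 and 6 adjusted over the list alone, adjusted p = 0.012, and 0.0592 with an estimated correlation) and plasma cell genes (8 rose and 3 fell of 19, 9 and 3 adjusted over the list alone, adjusted p = 0.0245, and 0.215 with an estimated correlation) were higher. In all 3648 genes were called, 1905 higher with NAC and 1743 lower, 57 and 45 of them by at least 2-fold, and 27 against a minimum fold of 1.5. Without NAC replicate 2 the count was 5131 and without VitC replicate 2 it was 2329. With libraries scaled to total reads 2725 were higher and 968 lower. Under that scaling 20 ribosomal protein genes were lower and 0 higher, and 25 MYC targets were lower and 6 higher. With the length and GC trends removed 4012 genes were called, 2838 of them in the same direction by the main test.

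In LY1, NAC raised stress genes that were close to absent in the controls and lowered sterol synthesis, cell cycle and MYC target genes. NIBAN1, a translation-linked stress gene, went from 2.21 ± 0.512 to 822 ± 46.8 normalized reads (ratio of reads 370, 95% interval 179 to 921). ATF3 went from 1.87 ± 1.87 to 472 ± 21.7 (248, 114 to 678) and INHBE from 0.967 ± 0.983 to 268 ± 13.4 (283, 96.4 to 1370). The kelch gene KLHDC7B (184, 71.4 to 676), the adhesion adaptor FERMT2 (103, 54.2 to 227), the epithelial splicing regulator ESRP1 (93.8, 64.3 to 143) and the sphingolipid transporter family gene SPNS3 (46, 28.2 to 81) also came up from near 0. CHAC1 rose 35.3-fold, from 22.7 ± 8.22 to 803 ± 41.2 (log2 change 5.14, standard error 0.197, adjusted p = 3.78e-09). Falls were smaller. The scaffold gene FRMD4B fell to 0.4 times control and HMGCS1, a synthase of the sterol pathway, to 0.407 times (from 5644 ± 56.6 to 2301 ± 127, adjusted p = 1.02e-33). The toll-like receptor homolog CD180 (0.416), the exocytosis gene CADPS (0.417), the desaturase SCD (0.421, from 6727 ± 53.5 to 2828 ± 15.4, adjusted p = 8.51e-37) and the sterol sensor partner INSIG1 (0.421) fell. So did RGS13 (0.460), a regulator of G protein signalling, and the receptor GPR18 (0.464).

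Lists rising in LY1 with NAC, with the preset and the estimated correlation, began with ATF4 targets: 41 of 42 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 4.82e-43). SESN2 stood at 2.48, TRIB3 at 1.98, WARS1 at 1.67 and SLC6A9 at 4.37. NRF2 targets rose (21 rose and 4 fell of 30, the same counts adjusted over the list alone, adjusted p = 2.2e-10), with FTH1 at 1.51, NQO1 at 1.48 and FTL at 0.97. Mitochondrially encoded messenger RNAs rose (12 of 13, the same counts adjusted over the list alone, adjusted p = 2.38e-18), with MT-ND2 at 1.39, MT-ND3 at 1.21 and MT-CYB at 0.55. NF-kappaB targets (20 rose and 6 fell of 28, the same counts adjusted over the list alone, adjusted p = 3.46e-07) included ICAM1 at 3.25 and RELB at 0.82, with REL at -0.78. Lysosome genes (18 rose and 7 fell of 35, 19 and 7 adjusted over the list alone, adjusted p = 0.000897) and collagen genes (8 rose and 1 fell of 12, the same counts adjusted over the list alone, adjusted p = 0.00276) rose. The unfolded protein response rose (16 rose and 8 fell of 32, 16 and 9 adjusted over the list alone, adjusted p = 0.00726), with XBP1 at 1.04, ERN1 at 1.7 and HERPUD1 at 0.74. Falling were sterol synthesis (29 of 31, the same counts adjusted over the list alone, adjusted p = 9.79e-22), with SQLE at -1.09, and MYC targets (7 rose and 49 fell of 73, 7 and 52 adjusted over the list alone, adjusted p = 1.99e-08). B cell receptor and identity genes fell (3 rose and 30 fell of 37, 3 and 31 adjusted over the list alone, adjusted p = 1.52e-09, CD38 -0.68, PLCG2 -0.50, CD22 -0.49). So did germinal centre genes (5 rose and 15 fell of 23, the same counts adjusted over the list alone, adjusted p = 0.000905, MME -0.85). G2/M and mitosis genes (10 rose and 43 fell of 60, the same counts adjusted over the list alone, adjusted p = 7.37e-09, KIF11 -0.54, SMC4 -0.53) fell. G1/S and replication genes fell (11 rose and 29 fell of 53, the same counts adjusted over the list alone, adjusted p = 0.00941, MCM4 -0.49). These were 13 of 20 called lists.

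Apoptosis and p53 genes in LY1 with NAC were mixed. The BCL2 family was not called (9 rose and 5 fell of 19, adjusted p = 0.0537), but its death-promoting members BBC3 (1.43, standard error 0.0991, adjusted p = 8.56e-17), BMF (0.84) and BAX (0.37) rose and BCL2 fell (-0.35). Of 29 caspase and death receptor genes 11 rose and 13 fell (adjusted p = 0.907): the death receptors FAS (3.13, standard error 0.216, adjusted p = 6.8e-17) and TNFRSF10B (0.89) rose and BIRC6 (-0.45) fell. Of 31 p53 targets 17 rose and 8 fell (17 and 9 adjusted over the list alone, adjusted p = 0.0139, and 0.0512 with an estimated correlation), with CDKN1A at 1.02 and RRM2B at -0.74. Immediate early genes rose with EGR1 (14 rose and 4 fell of 27, the same counts adjusted over the list alone, adjusted p = 0.0159, and 0.115 with an estimated correlation), among them IER5 (1.55) and JUND (0.64). Ribosomal proteins (57 rose and 8 fell of 78, 58 and 9 adjusted over the list alone, adjusted p = 4.34e-11, and 0.177 with an estimated correlation, RPLP1 0.39) and glutathione genes (17 rose and 6 fell of 35, 18 and 6 adjusted over the list alone, adjusted p = 0.00529, and 0.0878 with an estimated correlation, CTH 2.39) rose with the preset correlation only. So did the 7 tested germline genes (5 rose, the same counts adjusted over the list alone, adjusted p = 0.0457, and 0.132 with an estimated correlation). Glycolysis (2 rose and 15 fell of 20, the same counts adjusted over the list alone, adjusted p = 9.37e-05, and 0.0761 with an estimated correlation, LDHA -0.35, HK2 -0.53) fell with the preset correlation only. So did heat shock genes (7 rose and 14 fell of 25, the same counts adjusted over the list alone, adjusted p = 0.0307, and 0.0783 with an estimated correlation, HSPD1 -0.41).

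In LY1 with NAC 8461 of 15661 genes were called, 3959 higher and 4502 lower, 536 and 66 of them by at least 2-fold, and 432 against a minimum fold of 1.5. With the length and GC trends removed 7638 were called, 5993 of them in the same direction by the main test and 140 in the opposite direction. Germline (adjusted p = 0.201), immediate early (0.0671) and glutathione (0.0834) genes were then no longer called, and hypoxia targets (0.0309, against 0.216) and MHC class II genes (0.0309, against 0.116) were called. The median of G2/M genes was -0.135, against -0.213, and that of the unfolded protein response 0.189, against 0.0782.

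In LY1, VitC raised antioxidant genes and lowered sterol, B cell and replication genes. NQO1 rose 7.14-fold, from 475 ± 26.8 to 3396 ± 121 normalized reads (log2 change 2.84, standard error 0.0438, adjusted p = 6.43e-41). HMOX1 rose from 1101 to 4989 (log2 change 2.18, standard error 0.0308, adjusted p = 1.11e-43), and OSGIN1, an oxidative stress-induced growth inhibitor, 20.9-fold. HPD, the tyrosine-degrading dioxygenase, went from 4.49 ± 3.07 to 332 ± 15.8 (ratio of reads 74.7, 95% interval 44.3 to 137). CHAC1 rose 16.5-fold and the long non-coding RNA LUCAT1, annotated as antisense, 15.2-fold. SLC12A8 rose 10.9-fold, the adrenomedullin family gene ADM2 10.6-fold and the glycine transporter SLC6A9 9.17-fold. Lowest against control were the lectin CLEC17A (0.331), the imprinted gene PEG10 (0.361, from 8010 ± 71.8 to 2891 ± 18.1, adjusted p = 1.89e-40) and CADPS (0.364). The bicarbonate transporter SLC4A7 (0.405), the sterol exporter ABCA1 (0.428), SCD (0.439), the growth factor GDF11 (0.443) and the integrin ITGB8 (0.474) also fell.

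Of 30 NRF2 targets 27 rose and 2 fell in LY1 with VitC, the same counts adjusted over the list alone (adjusted p = 2.36e-22), with FTH1 at 1.92 and FTL at 1.63. Of 35 glutathione and thioredoxin genes 23 rose and 8 fell (24 and 8 adjusted over the list alone, adjusted p = 4.04e-05), with GSTP1 at 0.73 and GSR at 0.69. ATF4 targets (37 rose and 2 fell of 42, the same counts adjusted over the list alone, adjusted p = 5.83e-25, SESN2 1.56, TRIB3 1.22) and all 13 mitochondrially encoded messenger RNAs (the same counts adjusted over the list alone, adjusted p = 2.78e-23, MT-ND2 1.5, MT-CYB 0.95) rose. So did nuclear-encoded respiratory chain genes (57 rose and 9 fell of 76, the same counts adjusted over the list alone, adjusted p = 3.28e-08, COX6A1 0.32, COX4I1 0.24). NF-kappaB targets (18 rose and 6 fell of 28, the same counts adjusted over the list alone, adjusted p = 0.00336) included LTB at 1.27 and BATF at 1.86, with REL at -0.93. Lysosome genes (18 rose and 7 fell of 35, 19 and 7 adjusted over the list alone, adjusted p = 0.00103) included SQSTM1 at 1.16. Lower were sterol synthesis (3 rose and 25 fell of 31, 3 and 26 adjusted over the list alone, adjusted p = 3.83e-14, HMGCS1 -0.97, INSIG1 -1.03, SQLE -0.80) and B cell receptor and identity genes (3 rose and 29 fell of 37, 3 and 30 adjusted over the list alone, adjusted p = 9.41e-09, PAX5 -0.60, CD22 -0.53). Germinal centre genes (5 rose and 13 fell of 23, the same counts adjusted over the list alone, adjusted p = 0.0053, BACH2 -0.75) and G1/S and replication genes (4 rose and 34 fell of 53, the same counts adjusted over the list alone, adjusted p = 5.56e-05, MCM4 -0.58) were lower. So were ascorbate, dioxygenase and DNA methylation genes (5 rose and 17 fell of 28, 6 and 18 adjusted over the list alone, adjusted p = 0.00661, KDM5A -0.43, SLC23A2 -0.37). These 12 lists were called with the preset and the estimated correlation.

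Ribosomal proteins (72 rose and 1 fell of 78, the same counts adjusted over the list alone, adjusted p = 2.06e-22, and 0.111 with an estimated correlation, RPL28 0.38) rose in LY1 with VitC with the preset correlation only. So did collagen genes (8 rose and 2 fell of 12, the same counts adjusted over the list alone, adjusted p = 0.0415, and 0.139 with an estimated correlation) and histone genes (13 of 39 rose, 11 adjusted over the list alone, adjusted p = 0.0345, and 0.17 with an estimated correlation). G2/M genes fell (15 rose and 39 fell of 60, the same counts adjusted over the list alone, adjusted p = 0.000137, and 0.152 with an estimated correlation), with TOP2A at -0.49 and ECT2 at -0.60. MYC targets were not called although MYC fell (28 rose and 29 fell of 73, the same counts adjusted over the list alone, adjusted p = 0.572). The BCL2 family (10 rose and 6 fell of 19, adjusted p = 0.36) and caspase and death receptor genes (14 rose and 11 fell of 29, adjusted p = 0.929) were not called, with BAX (0.48) and PMAIP1 (0.43) higher and BCL2 (-0.26) and APAF1 (-0.71) lower. Immediate early genes (7 rose and 9 fell of 27, adjusted p = 0.929) and p53 targets (11 rose and 10 fell of 31, adjusted p = 0.895) were not called. TFRC fell (-0.75), as in Ramos, while the list of iron genes was not called (9 rose and 7 fell of 17, adjusted p = 0.165). In all 8762 of 15661 genes were called, 4132 higher and 4630 lower, 359 and 91 of them by at least 2-fold, and 323 against a minimum fold of 1.5. With the length and GC trends removed 7356 were called, 5546 in the same direction by the main test and 317 in the opposite direction. MYC targets were then called lower (11 rose and 39 fell of 73, adjusted p = 3.36e-05) and the unfolded protein response higher (adjusted p = 0.000296, against 0.157). MHC class II genes were called (0.0313, against 0.165), and the histone (0.317) and collagen (0.207) lists were no longer called. Respiratory chain genes stayed called with 36 higher and 7 lower and a median of 0.0681, against 0.142. Smaller medians were also left for glutathione (0.0998, against 0.219), germinal centre (-0.0594, against -0.203), dioxygenase (-0.0821, against -0.214) and G2/M genes (-0.0714, against -0.196).

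**Figure D2:**
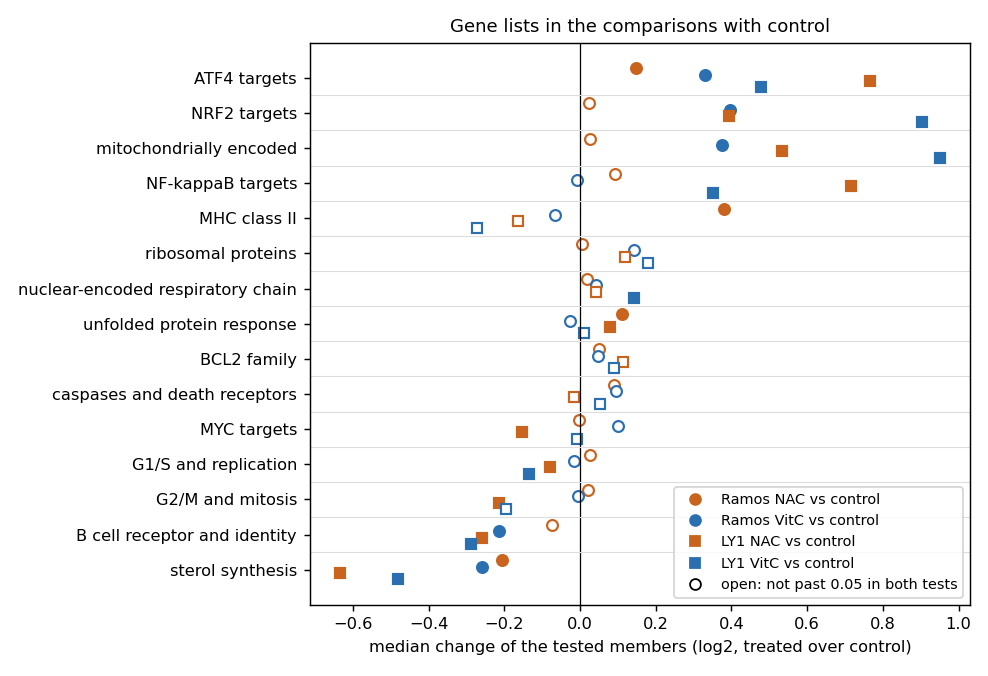
Median log2 change over control of the tested members of 15 gene lists, with circles for Ramos, squares for LY1, orange for NAC and blue for VitC. Filled symbols passed an adjusted p of 0.05 with the preset and the estimated correlation, and of the open ones the MYC, NRF2, mitochondrial, ribosomal and G2/M lists (Ramos NAC), BCL2 family (Ramos VitC), caspases (LY1 NAC) and unfolded protein response (LY1 VitC) change sign under another scaling or with the length and GC trends removed.

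Compared directly in LY1, NAC left ATF4 and NF-kappaB targets higher, and antioxidant, mitochondrial and MYC target genes lower, than VitC did. NQO1 stood at 0.391 times its VitC level with NAC (log2 change -1.35, standard error 0.0438, adjusted p = 1.5e-27), HMOX1 at 0.403, the secreted phosphoprotein SPP1 at 0.312, LUCAT1 at 0.338 and the pseudogene IFITM3P2 at 0.347. Higher with NAC were CLIP2, a microtubule linker (9.81-fold), KLHDC7B (8.44-fold, adjusted p = 1.51e-09), the purinergic receptor P2RX1 (6.83-fold), IGFBP4, a growth factor binding protein (6.59-fold) and FERMT2 (6.59-fold). With a pseudocount of 0.1 KLHDC7B was no longer called (adjusted p = 0.164, the highest of its alternatives). EGR1 was higher with NAC (log2 change 1.4, standard error 0.159). MYC was not called (log2 change 0.04, standard error 0.02, adjusted p = 0.142), and over its alternatives the adjusted p ran from 2.76e-05 to 0.463. It passed with libraries scaled to total reads (2.76e-05) and with the length and GC trends removed (0.00132). ATF4 targets (39 of 42 rose, 40 adjusted over the list alone, adjusted p = 1.19e-35) and NF-kappaB targets (16 rose and 2 fell of 28, the same counts adjusted over the list alone, adjusted p = 1.59e-05) were higher with NAC. So were p53 targets (13 rose and 6 fell of 31, 13 and 7 adjusted over the list alone, adjusted p = 7.17e-05) and immediate early genes (8 of 27 rose, the same counts adjusted over the list alone, adjusted p = 0.000156). Hypoxia targets (12 rose and 4 fell of 27, 13 and 4 adjusted over the list alone, 0.00293), G1/S genes (18 rose and 5 fell of 53, 21 and 5 adjusted over the list alone, 0.00807) and the ascorbate and dioxygenase list (11 rose and 4 fell of 28, 16 and 4 adjusted over the list alone, 0.0109) were also higher.

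Lower with NAC than with VitC in LY1 were NRF2 targets (1 rose and 22 fell of 30, 1 and 23 adjusted over the list alone, adjusted p = 1.72e-22) and mitochondrially encoded messenger RNAs (12 of 13 fell, the same counts adjusted over the list alone, 5.76e-23). Nuclear-encoded respiratory chain genes (54 of 76 fell, 57 adjusted over the list alone, 5.51e-14), MYC targets (4 rose and 49 fell of 73, 4 and 51 adjusted over the list alone, 4.15e-12) and glycolysis (1 rose and 17 fell of 20, the same counts adjusted over the list alone, 1.84e-11) were lower. Sterol synthesis (2 rose and 23 fell of 31, 2 and 24 adjusted over the list alone, 2.16e-10), heat shock genes (4 rose and 20 fell of 25, 4 and 21 adjusted over the list alone, 3.25e-07) and iron genes (3 rose and 8 fell of 17, the same counts adjusted over the list alone, 0.00186) were also lower. With the preset correlation only, ribosomal proteins (4 rose and 46 fell of 78, 4 and 49 adjusted over the list alone, 1.32e-10, and 0.22 with an estimated correlation) and G2/M genes (4 rose and 22 fell of 60, the same counts adjusted over the list alone, 0.0013, and 0.19 with an estimated correlation) were lower. Glutathione genes were lower (6 rose and 16 fell of 35, 0.0451, and 0.191 with an estimated correlation) and plasma cell genes higher (10 rose and 3 fell of 18, 10 and 4 adjusted over the list alone, 0.017, and 0.0621 with an estimated correlation). In all 5741 genes were called, 2980 higher with NAC and 2761 lower, 294 and 77 of them by at least 2-fold, and 157 against a minimum fold of 1.5. With libraries scaled to total reads 4748 were higher and 1478 lower, and the medians of the iron and G2/M lists turned positive (0.0098 and 0.00844). Then 13 glutathione genes rose and 12 fell, with 14 and 17 ribosomal protein genes, 14 and 8 G2/M genes and 6 and 7 iron genes. Respiratory chain genes stood at 3 higher and 23 lower under that scaling, MYC targets at 8 and 28, and G1/S genes at 36 and 1.

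Some genes moved the same way in all 4 comparisons with control, stress and sterol genes among them. Of 13734 genes tested in both lines, 138 were called higher in all 4 and 163 lower. Both treatments raised 242 of these genes in Ramos and 2401 in LY1 and lowered 359 and 3343. If the lines, which share no library, were independent, 42.3 higher and 87.4 lower were expected. That value takes every tested gene as equally likely to be called. Changes also fell with transcript length in all 4 comparisons (rank correlations of -0.154 to -0.428), which can add to such an overlap. These counts were not made with the trends removed. DDIT4 rose in each (1.58 and 2.07 with NAC and VitC in Ramos, 1.81 and 1.26 in LY1), as did CHAC1 (0.56, 1.09, 5.14 and 4.04) and ATF3, SESN2, TRIB3, WARS1 and PSAT1 of the ATF4 targets. NQO1, HMOX1, FTH1 and FTL of the NRF2 targets rose in each, as did the NF-kappaB target PLEK and the mitochondrial ribosomal RNA MT-RNR1 (0.77, 1.79, 2.31 and 2.31). HMGCS1, FASN, SCD, SQLE, INSIG1 and LSS of sterol and fatty acid synthesis fell in each, with the B cell genes PAX5, SYK and CD22 and the methylation cofactor UHRF1.

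**Figure D3:**
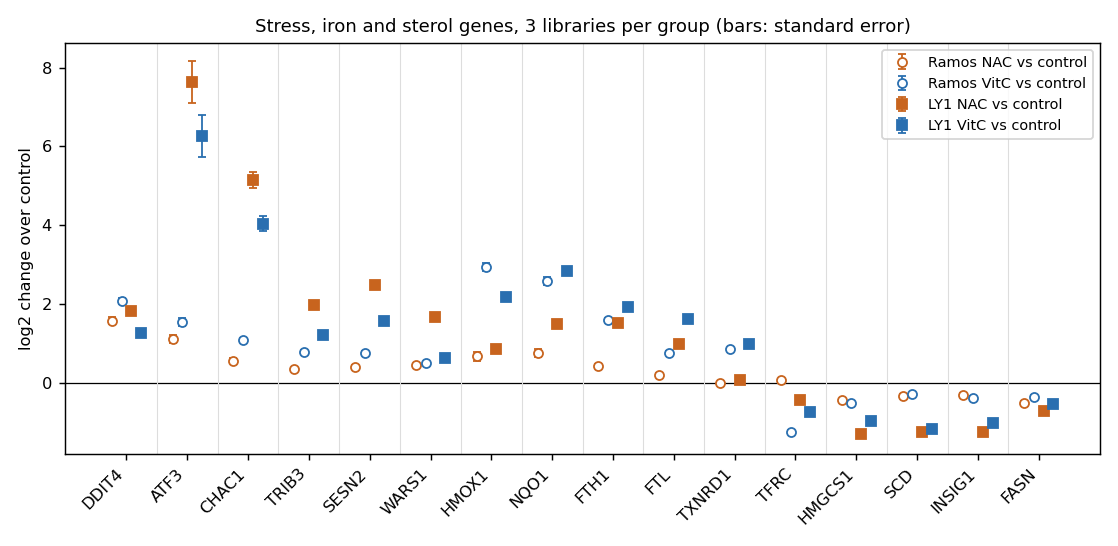
Log2 change over control with standard error (3 libraries per group) of 16 stress, iron and sterol genes with NAC (orange) and VitC (blue) in Ramos (open circles) and LY1 (filled squares). ATF3 stood near 0 in LY1 controls, so its plotted change depends on the pseudocount of 1.

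The 2 treatments of a line share its controls, so no chance value is given for the genes called with both. In LY1, 2669 genes rose with both and 3485 fell with both, and 264 moved in opposite directions. The correlation of log2 changes was 0.744 and their covariance 0.183. Simulated unchanged groups that shared controls gave 0.482 and 0.0111. In Ramos 259 rose and 392 fell with both and 89 moved oppositely. The correlation was 0.422 and the covariance 0.0281, against 0.506 and 0.0123 in the simulation. The simulated groups held noise and no treatment effect, so their correlations are no baseline for the real ones. The covariances can be set side by side, and in both lines the real one was larger. Across lines, which share no libraries, VitC moved 784 genes up and 738 down in both (313 and 377 expected) and 224 oppositely (689 expected), with a correlation of 0.431. NAC moved 348 up and 548 down in both (284 and 341 expected) and 628 oppositely (627 expected), with a correlation of 0.171. With NAC the change ran oppositely with GC share in the lines (rank correlation -0.362 in Ramos and 0.443 in LY1). With the length and GC trends removed NAC moved 495 up and 573 down in both lines, and VitC 915 and 844. No expected values were computed for these.

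The NAC effect differed between the lines for 5759 of 17111 genes, in all 18 libraries on a joint scale. MYC differed by 0.26 (standard error 0.0365, adjusted p = 7.67e-06), being unchanged in Ramos and lower in LY1, and EGR1 by -1.68 (standard error 0.224, adjusted p = 4.18e-06), the rise being in LY1. The signed difference (Ramos minus LY1) was lowest for genes that came up from near 0 in LY1, namely NIBAN1 (-8.01, absent from Ramos controls), ATF3 (-6.53), KLHDC7B (-6.47), INHBE (-6.34) and P2RX1 (-5.41, from -0.387 in Ramos and 5.03 in LY1). These values depend on the pseudocount. It was highest for STXBP6, a SNARE-binding gene (2, from 0.889 in Ramos and -1.11 in LY1) and GPR18 (1.72, from 0.616 and -1.11). It was 1.58 for the transcription factor SOX4 (from 1.03 and -0.547), 1.49 for CLEC17A (from 0.574 and -0.914) and 1.49 for the lipid antigen receptor CD1C (from 0.0507 and -1.44, adjusted p = 0.0369). Of these the change itself was larger in Ramos only for SOX4. CD1C rested on a fall from 18.7 to 7.15 reads in LY1 and was not called in 10 of 12 fits without 1 library (adjusted p = 0.0546 to 0.0776, all but those without Ramos control replicate 3 or LY1 NAC replicate 1), nor with no filter (0.103), the trends removed (0.0606) or a pseudocount of 0.1 (0.137, the highest of its alternatives). By edgeR NIBAN1, at 0 in Ramos controls and NAC, was not called (adjusted p = 1). Lists were only counted here: the signed effect was lower in Ramos for 40 of 44 ATF4 targets (42 adjusted over the list alone) and 12 of 13 mitochondrially encoded messenger RNAs (the same counts adjusted over the list alone). It was higher for 25 of 31 sterol synthesis genes (26 adjusted over the list alone), 37 of 60 G2/M genes (38 adjusted over the list alone) and 32 of 73 MYC targets (the same counts adjusted over the list alone). Of the 5759, 3185 were higher in Ramos and 2574 lower, 101 and 594 of them by at least 2-fold, and 240 passed against a minimum fold of 1.5. The rank correlation of the difference with GC share was -0.569. The list counts were not made with the trends removed. Within the lines, removing them moved the median of G2/M genes with NAC from -0.213 to -0.135 in LY1 and from 0.0204 to -0.0309 in Ramos. With the trends removed 4701 were called, 3339 of them in the same direction by the main test and 35 in the opposite direction.

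The VitC effect differed between the lines for 4533 of 17111 genes. MYC differed by 0.58 (standard error 0.0365, adjusted p = 2.12e-10), rising in Ramos and falling in LY1, and EGR1 was not called (-0.36, standard error 0.224, adjusted p = 0.262). The signed difference was lowest for ATF3 (-4.74), INHBE (-4.62), CHAC1 (-2.97), SPNS3 (-2.87) and P2RX1 (-2.85, from -0.6 in Ramos and 2.25 in LY1). All but CHAC1 stood at 7.29 reads or fewer in LY1 controls, so these values depend on the pseudocount. The amino acid transporter SLC38A2 differed by 1.42 (standard error 0.114, adjusted p = 1.56e-08), rising from 305 to 489 reads in Ramos and falling from 3004 to 1809 in LY1. The other large differences were in genes with few reads in Ramos, so their size depends on the pseudocount. They were aldehyde oxidase AOX1 (2.1, adjusted p = 0.00174, 6.25 reads in Ramos controls) and ELAPOR1, an endosomal gene (1.82, adjusted p = 0.0346). Also among them were the p53-responsive RNA PURPL (1.5, adjusted p = 0.00199) and the Hippo pathway coactivator WWTR1 (1.48, adjusted p = 0.0249). With a pseudocount of 0.1 the differences were 3.14 for ELAPOR1, 2.72 for PURPL and 3.27 for WWTR1. ELAPOR1 was not called in 8 of 12 fits without 1 library (0.0521 to 0.0886, all but those without Ramos control replicate 3, Ramos VitC replicate 2, LY1 control replicate 3 or LY1 VitC replicate 2) or with replicate number as a block (0.0631). Nor was it called with the trends removed (0.0739), no filter (0.109) or a pseudocount of 0.1 (0.199, the highest of its alternatives). PURPL was not called by DESeq2 (0.147, the highest of its alternatives), by edgeR (0.106) or with a pseudocount of 0.1 (0.0811). WWTR1 was not called without Ramos VitC replicate 1 (0.0838), LY1 control replicate 3 (0.0545) or LY1 VitC replicate 3 (0.055). Nor was it called by DESeq2 (0.0573), with the trends removed (0.0545) or with a pseudocount of 0.1 (0.197, the highest of its alternatives). Lists were again only counted. Over all 17111 genes tested the signed effect was higher in Ramos for 2561 and lower for 1972. It was higher for 31 of 73 MYC targets and lower for 3 (33 and 3 adjusted over the list alone). It was lower in Ramos for 21 of 44 ATF4 targets and higher for 6 (25 and 6 adjusted over the list alone), and lower for 24 of 76 respiratory chain genes and higher for 3 (28 and 3 adjusted over the list alone). Of the 4533, 2561 were higher in Ramos and 1972 lower, 74 and 353 of them by at least 2-fold, and 78 passed against a minimum fold of 1.5. The rank correlation of the difference with GC share was -0.518. The list counts were not made with the trends removed. With the trends removed 3432 were called, 2459 of them in the same direction by the main test and 1 in the opposite direction.

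Untreated Ramos and LY1 differed for 13394 of 17111 genes, 6497 higher in Ramos and 6897 lower, 2952 and 3124 of them by at least 2-fold and 6739 passing against a minimum fold of 1.5. Line and batch cannot be told apart here. MYC was higher in Ramos (log2 difference 0.22, standard error 0.0258), and EGR1 was not called (-0.29, standard error 0.159, adjusted p = 0.103). Most MHC class II genes were higher in Ramos (12 of 13, and 1 lower). As 5 of the 13 passed the filter in LY1, the size of the difference depends on the pseudocount for the rest, with HLA-DPA1 at 1 read in all LY1 controls and 14626 in Ramos (ratio 15500, 95% interval 2790 to 614000). The homeobox gene CUX2 was at least 7900-fold higher in Ramos, and CIBAR2, a ciliary gene, and the leukocyte receptor LILRB1 at least 2490-fold each, all without a read in LY1 controls (against 3 reads over the group). The synaptic gene PACSIN1 (ratio 2830, 95% interval 1740 to 4950) was higher in Ramos. The tubulin TUBB4A (1420, 773 to 2960), the focal adhesion genes TNS3 (1800, 771 to 5550) and TES (1060, 538 to 2460), the zinc finger gene ZBTB38 (977, 559 to 1890) and the collagen COL3A1 (4960, 889 to 196000) were higher in LY1. Ramos control replicate 3 held 109 reads of 38 of 54 genes of LY1 that stood at a median of 0 reads over the Ramos libraries, 0.193% of their LY1 level, against at most 0.0318% in the other Ramos libraries. The Ramos level of TUBB4A, TNS3, TES and ZBTB38 rested largely on this library. ATF4 targets were higher in untreated Ramos (33 higher and 8 lower of 44, 34 and 8 adjusted over the list alone), as were NF-kappaB targets (23 and 5 of 31), while respiratory chain genes (15 and 50 of 76), heat shock genes (2 and 20 of 25) and histone genes (3 and 29 of 41) were lower.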

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

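The tests of the mitochondrial messenger RNAs and of EGR1 and the length and GC correction were chosen after the results were seen, and the minimum of 20 reads in the mitochondrial tests was set after a run without it. The NAC effect differed between Ramos and LY1 for 5759 genes by a test of the difference itself, on 18 libraries. The libraries of each arm were also split in other ways between the lines, with line means taken out. Of 100 splits 1, the real one, called as many genes, and the highest of the others called 3308. A chance labelling of these libraries therefore rarely gives such a count. As the libraries of a group may be technical, the splits cannot exclude chance differences between cultures. The difference (Ramos minus LY1, log2) was 0.261 for MYC (standard error 0.0365, adjusted p = 7.67e-06), with 0.0249 in Ramos and -0.236 in LY1, and -1.68 for EGR1 (0.224, 4.18e-06), with -0.484 and 1.2. It was 2 for STXBP6, 1.72 for GPR18, 1.58 for SOX4, 1.49 for CD1C and 1.49 for CLEC17A. It was -8.01 for NIBAN1, -6.53 for ATF3, -6.47 for KLHDC7B, -6.34 for INHBE and -5.41 for P2RX1, values that depend on the pseudocount because these genes stood at 0.966 to 7.29 reads in LY1 controls.

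The VitC effect differed between the lines for 4533 genes by the same test. Here 1 of 100 splits, the real one, called as many, with 705 as the highest of the others, and the same limit holds. The difference was 0.577 for MYC (standard error 0.0365, adjusted p = 2.12e-10), with 0.301 in Ramos and -0.275 in LY1. It was 2.1 for AOX1, 1.82 for ELAPOR1, 1.5 for PURPL, 1.48 for WWTR1 and 1.42 for SLC38A2. All of these but SLC38A2 stood at 6.25 reads or fewer in Ramos controls, so that their values depend on the pseudocount. The difference was -4.74 for ATF3, -4.62 for INHBE, -2.97 for CHAC1, -2.87 for SPNS3 and -2.85 for P2RX1. All of these but CHAC1 stood at 7.29 reads or fewer in LY1 controls, so that their values depend on the pseudocount too. Within each line and between the controls, 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real splits called 2380, 2507 and 3648 genes in Ramos (NAC, VitC and NAC against VitC), 8461, 8762 and 5741 in LY1 and 13394 between the controls, in each case 1 of the 10, and the highest of the other splits called 0 by limma-trend.

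More genes were called in LY1 than in Ramos, 8461 against 2380 with NAC and 8762 against 2507 with VitC. With only the compared groups fitted the counts were 8713 against 1887 and 8629 against 4056. Without NAC replicate 2 the Ramos count with NAC was 3309. With all libraries thinned to 20188487 reads LY1 still had 3.62 and 3.55 times as many calls, which argues against depth. With the standard errors of Ramos put in place of its own, over the 13734 genes tested in both lines, it had 2.94 and 3 times as many. This argues against a smaller replicate spread as the whole cause. The LY1 calls fell from 7771 to 6604 with NAC and from 8103 to 7134 with VitC, so spread can be a part. The explanations were not tested together. With the length and GC trends removed it had 3.32 and 2.26 times as many, which argues against these trends as the whole cause. A batch that goes with the line cannot be told apart from the line, and a stronger response of LY1 cells at these doses, with the dose relative to each line's sensitivity unknown, is an open hypothesis that was not tested.

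Mitochondrially encoded messenger RNAs were higher in Ramos with VitC and in LY1 with NAC and VitC. If more RNA without a poly(A) tail had been kept, replication histones would have risen as much, unless something else lowered them. Their median change lay below that of the mitochondrial messenger RNAs by -0.388 (upper bound -0.238), -0.336 (-0.0178) and -0.614 (-0.15). If damaged cells had lost cytoplasmic RNA, nuclear sense intronic RNAs would have risen as much, but they lay below by -0.497 (-0.402), -0.554 (-0.24) and -0.952 (-0.468). The bounds came from resampling genes, not libraries. They treat genes as independent and leave out the spread between libraries. For these genes the intronic test argues against lost cytoplasmic RNA as the whole cause in each of the 3 comparisons. The histone test argues against kept RNA as the whole cause in Ramos with VitC, where G1/S genes were called lower only with the trends removed. In LY1 it cannot decide. G1/S and replication genes were lower there (11 rose and 29 fell with NAC, 4 and 34 with VitC), and replication-dependent histones may have been held down with them. The histone test was weakest in LY1 with NAC (-0.0178). Other values went both ways. The histone medians were -0.0143, 0.198 and 0.338, and the mitochondrial ribosomal RNAs rose more than the median messenger RNA (MT-RNR1 by 1.79, 2.32 and 2.31, MT-RNR2 by 1.15, 1.24 and 1.26, against 0.374, 0.534 and 0.952). The mitochondrial transfer RNAs did not rise as much (medians -0.0989, 0.108 and -0.216). Kept RNA as a part of the cause stays open. A change in mitochondrial transcription or RNA turnover stays open as a hypothesis.

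EGR1 was higher with NAC in LY1 and in none of the other comparisons with control. Without any 1 of the 6 libraries its highest adjusted p was 2.35e-06 (log2 change 1.11 to 1.3), so no single library carried it. The ratio of summed reads was 2.32 with an exact 95% interval of 1.92 to 2.82, which argues against counting error. Of 26 other immediate early genes tested, 13 were higher and 4 lower. Over all genes 3959 of 15661 were called higher, so some rises were likely in any list and this count cannot decide. The list was not called with an estimated correlation, nor with the length and GC trends removed (list adjusted p = 0.0671). Handling of the NAC cultures at harvest cannot be told apart from a response to NAC, since all NAC libraries may share it. A response of EGR1 to NAC is an open hypothesis.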

How the results depend on the processing

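The edgeR test and the length and GC correction were added after the data were seen, and all other alternatives were planned. Each of 297 gene results named in the text was refitted under the alternatives other than the minimum fold, 5381 refits in all. In 5329 the call and direction were the same, and no direction turned. In 45, for 10 results, the call was lost, and in 7, for 3 results, a call was gained. Genes other than MYC and EGR1 were named for large changes or small adjusted p in these libraries, so this stability was partly built in. Over all genes, with the length and GC trends removed, 1475 of 2380 calls in Ramos with NAC kept call and direction. In LY1 140 calls with NAC and 317 with VitC turned. Against the minimum fold 143 of the 297 lost their call. Counts of called genes stayed within 1.5 times under TMM, total reads, both filters, DESeq2, edgeR, limma-voom, the replicate block, all 18 libraries in 1 fit, a pseudocount of 0.1 and the length and GC correction. By DESeq2 they were 1894, 2016, 2965, 7019, 7266, 4149, 4948, 3990 and 13777 (Ramos NAC, Ramos VitC, Ramos NAC against VitC, the same for LY1, NAC effect, VitC effect, controls) and by edgeR 2403, 2533, 3695, 8643, 8746, 5795, 5662, 4452 and 13424. With the replicate block they were 2452, 2644, 3783, 8434, 8731, 5693, 5704, 4501 and 12439. Against a minimum fold of 1.5 they fell to 7, 33, 27, 432, 323, 157, 240, 78 and 6739, and the same-direction overlaps to 5 (Ramos), 167 (LY1), 6 (NAC) and 25 (VitC) from 651, 6154, 896 and 1522. With only the compared groups fitted Ramos VitC gave 4056. That fit leaves out the NAC libraries, which varied most in Ramos (median SD of log2 values 0.101, against 0.0702 in controls and 0.0704 with VitC). Whether this raised the count was not tested. With 1 library left out, which also leaves fewer samples, counts ran from 1123 to 3309 (Ramos NAC), 1488 to 1783 (Ramos VitC), 2329 to 5131 (Ramos NAC against VitC), 7728 to 7922, 8039 to 8480 and 4855 to 5452 (LY1), 5112 to 6453 (NAC effect), 3849 to 4552 (VitC effect) and 13077 to 13163 (controls), and list calls from 12 to 16, 14 to 16, 19 to 21 and 14 to 17. Called lists numbered 12, 16, 20 and 16 with the preset correlation and 4, 6, 13 and 12 with the estimated one, which widens the error of lists whose members vary together, and 20, 16, 29 and 27 with fry, which tests each list alone. With the length and GC correction 11, 16, 19 and 17 lists and 2299, 3256, 4012, 7638, 7356, 5572, 4701 and 3432 genes were called. With total reads the share of higher genes moved from 47.9 to 31% (Ramos VitC), from 52.2 to 73.8% (Ramos NAC against VitC) and from 51.9 to 76.3% (LY1 NAC against VitC). In the differences between lines CD1C, ELAPOR1, PURPL and WWTR1 lost their call under several settings.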

Other observations

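Few markers of other cell types passed the filter. Of the myeloid markers 1 was tested in each line and of the stromal and epithelial markers 3 in Ramos and 4 in LY1, too few for a test, and the 12 T and NK cell markers tested in LY1 were not called (1 rose and 5 fell with NAC, adjusted p = 0.354, and 3 rose and 4 fell with VitC, adjusted p = 0.905). In Ramos 5 T and NK cell markers were tested and were called lower with VitC (0 rose and 2 fell, adjusted p = 0.0474, and 0.0109 with the length and GC trends removed), though not with an estimated correlation (0.14), and not with NAC (adjusted p = 0.347). Of 6 metallothionein and zinc genes tested in LY1, 3 rose and 2 fell with NAC (adjusted p = 0.631) and with VitC (adjusted p = 0.673).

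Ramos control replicate 3 held 109 reads from 38 of 54 genes of LY1 that stood at a median of 0 reads over the Ramos libraries, 0.193% of their LY1 level. The other 8 Ramos libraries held 0.00641 to 0.0318%, and the LY1 libraries held 0.00567 to 0.0298% of the Ramos level of 44 genes of Ramos chosen in the same way. Mitochondrial transfer RNAs were mixed. With VitC 3 rose and 6 fell of 17 tested in Ramos and 5 rose and 8 fell of 19 in LY1, where the median messenger RNA rose, and with NAC 5 rose and 0 fell in Ramos and 6 rose and 4 fell in LY1.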
